A study of Mus musculus with 14 samples.

How the data were processed

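RNA from mouse spleen cells was measured on 14 oligonucleotide arrays of 3 array sets, called A, B and C here after the letters in the labels. Per the labels, the cells were either enriched for follicular dendritic cells (FDC), the stromal cells that hold antigen in B cell follicles, or depleted of them. Array set A held depleted samples 1 and 2 and enriched samples 1, 2 and 3, set B held depleted 1 and 2 and enriched 2 and 3, and set C held the same 5 samples as set A. The isolation protocol, the animals and the scanner settings are not given in the sources used here. Nothing in the labels says that samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

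The authors deposited 1 table of linear intensity values per array set, with 1 value per probe set and array. How these intensity values were summarised, background-corrected and scaled is not given in the sources used here. The tables held 12488, 12477 and 11934 probe sets for A, B and C. Enriched sample 2 on set A had no value for 893 probe sets, which were fitted on the remaining arrays. The 2%-trimmed means of the arrays of a set, over probe sets with a value on every array, differed by a factor of 1.08 on A, 1.03 on B and 1.02 on C. As this lay within the 10% set before the data were examined, the deposited scale was kept. The number of arrays limits the precision of every value.

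Probe sets were named through the annotation of each array set, with symbols updated through the Entrez identifier to the gene table of assembly GRCm38.p6. Of the probe sets other than array controls, 10833 on A, 10581 on B and 7717 on C had 1 gene symbol, 396, 178 and 150 had several, and 1193, 1652 and 4001 had none. Of those with 1 symbol, the identifier was found in that gene table for 10817, 10550 and 7677, and the rest kept their old symbol. Probe sets with several symbols were named after none. No genomic positions are given because the tables name no genome build.

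Each array set was fitted alone. Negative intensities were set to 0, and log2(intensity + pseudocount) was taken with the 20th percentile of the positive values of the set as pseudocount, 88.49 on A, 81.23 on B and 53.13 on C. Fold changes are on this scale, which understates the change of dim genes. A probe set was tested if it lay above the 40th percentile of the array on at least 2 arrays, and the 66 array controls of each set were left out. Differences were tested two-sided with limma 3.58.1 (lmFit and eBayes with a trended prior variance) in R 4.3.3, with Benjamini-Hochberg adjustment within the set. A probe set passed at an adjusted p under 0.05. With 2 depleted and 3 enriched arrays an exact permutation test of 1 gene cannot go below 0.1, and with 2 against 2 not below 0.333. Means of intensities are given with their SD.

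The 31 gene lists were fixed before the data were examined, and cover markers of the cell types a spleen fraction could hold and pathways. List members were counted as genes that rose, fell or did not pass, with the brightest tested probe set of a gene standing for it. A gene on several array sets was taken from the set where that probe set ranked highest in level. Lists with at least 5 genes on an array set were tested two-sided with camera at a preset inter-gene correlation of 0.01, giving 46 tests of 29 lists that were adjusted together. Camera with an estimated correlation and fry were run beside it. Camera sets the genes of a list against the other genes, whereas fry asks whether the genes of a list change at all. Where many probe sets pass, a list can pass fry without moving against other genes. With an estimated correlation, the degrees of freedom of camera come from the few arrays of a set, so its p-value can hardly fall far. The endothelium list on set B went from an unadjusted camera p of 2.84e-10 to 0.0226 at an estimated correlation of -0.025. A call lost in this form therefore does not decide whether correlated genes made the call. The genes named in the text were chosen by a rule set before the data were examined. It took the 12 largest rises and falls on set A and the 5 largest on B and C among passing probe sets with 1 gene whose groups did not overlap, leaving out immunoglobulin and T cell receptor segments and clone names. It also took the tested members of the FDC lists, up to 4 passing members of every other list, and the reference genes Ptprc, Actb and Gapdh. Where a gene outside the rule is named, the text says so. Gapdh had no tested probe set of its own. Of 131 genes named by the rule, 59 had over 1 tested probe set, and for 1 of them, Mcm5, probe sets passed in opposite directions.

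The scripts were tested on simulated data with the mean level of each probe set and 200 probe sets changed by 1.5-, 2- or 4-fold. The spread of a probe set was taken on the scale with the pseudocount but applied to log2 intensity without it. This gives dim probe sets too little spread. Noise was drawn independently for each value, and far fewer probe sets changed than passed in the data. The recovered shares and false calls may thus be better than on the real arrays. On set A, over 7575 simulated probe sets, 71.6% of the 1.5-fold, 94% of the 2-fold and 100% of the 4-fold changes were recovered. On set B, over 7523, these shares were 85.1%, 92.5% and 100%, and on set C, over 7238, they were 86.6%, 97% and 100%. No simulated change was called in the wrong direction, and 8, 5 and 10 unchanged probe sets were called on A, B and C. A 4-fold change was fitted as 3.06-fold on A, 3.15-fold on B and 2.98-fold on C at the median. In 20 simulated lists of 20 genes, the 1 list moved by 1.5-fold was found on every set, and 1 unmoved list was called on A. The genes of these lists were simulated as independent, with the median spread of the set for each. Estimated correlations in the real lists ran from -0.202 (endothelium, set C) to 0.803 (B cell, set B). The list simulation therefore does not test the preset correlation of 0.01. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

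The alternatives were quantile normalization, scaling to the median array, other pseudocounts, a floor, other filters, other prior variances, array weights, each sample left out, the replicate number as a block, adjustment over all array sets, other thresholds, the samples present on every set, and other list tests. A fit with enriched sample 1 as the only enriched array was added after seeing the data, because the biotinylated control transcripts of set A read 1910 and 2030 on the depleted arrays and 1830 on enriched sample 1, against 1430 and 1400 on enriched samples 2 and 3. In that fit the spread comes from the 2 depleted arrays alone, and the lone enriched array is assumed to vary like them. Without depleted sample 1 or 2, the lone depleted array is assumed to vary like the enriched ones. On set B, leaving out enriched sample 2 or 3 leaves 1 enriched array, which is assumed to vary like the depleted ones.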

Results

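The arrays compared mouse spleen cells enriched for FDC with spleen cells depleted of FDC, to find the genes whose RNA goes with the enriched fraction. The 14 arrays fell into 5 on set A (2 depleted and 3 enriched), 4 on set B (2 and 2) and 5 on set C (2 and 3). Median intensities were 244 and 250.8 on the depleted and 264.7 to 279 on the enriched arrays of set A. They were 200.2 and 202 against 206.9 and 208.8 on set B, and 123 and 123.8 against 125.5 to 126.3 on set C. Every enriched array thus had a higher median than every depleted array of its set, an offset that the deposited scale keeps. Arrays of the same group had Spearman correlations across probe sets of 0.9865 to 0.9954, and arrays of different groups of 0.9087 to 0.9697.

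Known FDC markers rose in the enriched fraction. Of the 14 tested members of the list of FDC markers kept apart from those shared with B cells, 10 rose, none fell and 4 did not pass, and 11 rose when adjusted over the list alone. The rise was not particular to this list. Its median log2 fold change of 0.844 lay above that of the macrophage list (0.744) and below those of the matrix (1.332) and endothelium (2.28) lists. Cxcl13, the chemokine that draws B cells into follicles, rose 11.9-fold, from an intensity of 32.4 ± 9.11 (SD, n = 2) to 1358 ± 192 (SD, n = 3). Clu, the chaperone clusterin, rose 11.2-fold, from 445.7 ± 32.8 (SD, n = 2) to 5906 ± 501 (SD, n = 3). Mfge8, a bridging protein for the uptake of dying cells, rose 5.44-fold, from 1441 ± 107 (SD, n = 2) to 8249 ± 880 (SD, n = 3), and the prion protein gene Prnp rose 5.11-fold. Il6 rose 3.83-fold, the matrix gene Postn 3.59-fold, the TNF receptor gene Tnfrsf1a 1.95-fold and the adhesion molecule gene Vcam1 1.65-fold at its brightest probe set. The other Vcam1 probe sets rose 4.67- and 3.24-fold. Madcam1 rose 1.27-fold and Ltbr, the lymphotoxin beta receptor gene, 1.17-fold. Ngfr, Tnfsf13b, Ntrk3 and Sox9 did not pass, with log2 fold changes of 0.16, 0.11, -0.03 and -0.08. Bst1, Pdpn and C4b lay below the filter on dim probe sets.

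**Figure D1:**
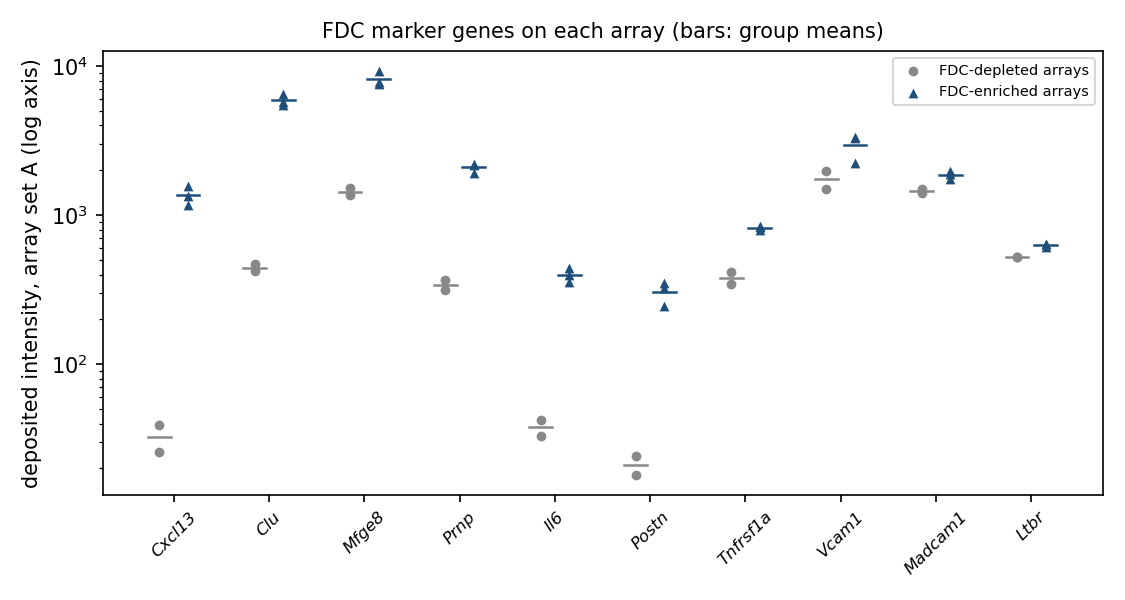
Deposited intensity (log axis) of the 10 FDC marker genes that rose on array set A, with a point per array and a bar at each group's mean, for 2 depleted and 3 enriched arrays. The enriched arrays lie above the depleted arrays for each gene, with the widest gap for Cxcl13 (32.4 against 1358) and a narrow one for Ltbr (526.1 against 632.1).

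The FDC marker list moved up against other genes on set A (camera, adjusted p = 2.86e-05), a call lost with an estimated correlation (adjusted p = 0.348). The calls of Madcam1, Ltbr and the brightest Vcam1 probe set were not stable. The other Vcam1 probe sets passed with adjusted p = 6.87e-06 and 6.23e-05 (limma) in the main fit and were not put through the other settings. Without depleted sample 1 the adjusted p was 0.115 for Vcam1, 0.127 for Madcam1 and 0.171 for Ltbr. Without depleted sample 2 it was 0.059 for Madcam1 and 0.166 for Ltbr, and without enriched sample 2 or 3 Ltbr had 0.0549 and 0.0563. Under quantile normalization Madcam1 (0.0538) and Ltbr (0.203) did not pass, and Ltbr did not pass with scaling to the median array (0.138) or with the replicate number as a block (0.0832). On set B, Ngfr passed without enriched sample 2 (0.0295), a fit with 1 enriched array assumed to vary like the depleted ones.

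Markers that FDC share with B cells did not move together. Of 8 tested genes, 1 rose, 4 fell and 3 did not pass, with the same counts adjusted over the list alone. Icam1, an adhesion molecule gene, rose 4.73-fold. The low-affinity IgE receptor gene Fcer2a fell 2.79-fold, Cxcr5, the receptor for Cxcl13, 2.03-fold, the complement receptor gene Cr2 1.34-fold and Cd40 1.15-fold. The log2 fold changes of Cr1l, Cd55 and Fcgr2b were 0.15, 0.07 and -0.09, and none of these passed at the brightest probe set. Another Cd55 probe set, on set A, fell with a log2 fold change of -0.56 (adjusted p = 0.0222). Cr2 did not pass without depleted sample 1 (adjusted p = 0.0973), nor Cd40 without depleted sample 1 (0.169), depleted sample 2 (0.274) or enriched sample 3 (0.109). Cd40 also missed the threshold with no filter (0.0634), with adjustment over all array sets (0.0514) and with the replicate number as a block (0.138). Cr1l passed with enriched sample 1 as the only enriched array (0.0205).

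Of 5 tested genes tied to FDC by the study or by work that followed it, 3 rose and 2 did not pass, and 4 rose when adjusted over the list alone. The study can have chosen some of these genes on these samples, so the list is not independent evidence of direction. Coch, which encodes the secreted protein cochlin, rose 10.2-fold from 14.4 ± 3.41 (SD, n = 2) to 973.1 ± 221 (SD, n = 3), and Apoe, the apolipoprotein E gene, rose 2.77-fold to 8971 ± 661 (SD, n = 3). Serpina1b rose 1.35-fold and did not pass without depleted sample 1 (adjusted p = 0.0828) or 2 (0.0909). Mdk had a log2 fold change of 0.27 with adjusted p = 0.0666. It passed without enriched sample 2 (0.037), with array weights (0.0106) and with enriched sample 1 as the only enriched array (0.000875). Serpina1a had a log2 fold change of 0.01 and did not pass.

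Endothelial genes rose throughout. All 21 tested members of the endothelium list rose, also when adjusted over the list alone, with a median log2 fold change of 2.28. Tie1, an endothelial receptor kinase gene, rose 16.7-fold, Sox17, a transcription factor gene of arterial endothelium, 15.5-fold, Cldn5, of endothelial tight junctions, 13.1-fold, and Eng 13.1-fold to an intensity of 7161 ± 257 (SD, n = 3). Plvap, which forms the diaphragms of fenestrated endothelium, rose 14.8-fold on set B at its brightest probe set and 23.4-fold at another. The list moved up on set A (camera, adjusted p = 2.16e-11), set B (2.61e-09) and set C (5.81e-06). With an estimated correlation the adjusted p values were 0.307, 0.26 and 0.26.

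Extracellular matrix and fibroblast genes also rose. Of 32 tested matrix genes 24 rose, none fell and 8 did not pass, with the same counts adjusted over the list alone. The proteoglycan gene Bgn rose 22.8-fold on set C and 13-fold on set A, and Col4a1, a basement membrane collagen gene, 18.3-fold. The matrix list moved up on set A (camera, adjusted p = 8.85e-12) and set C (0.000727), with adjusted p = 0.26 and 0.3 with an estimated correlation. Of 15 reticular fibroblast genes 13 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone. The contractile genes Acta2 and Myl9 rose 10.9- and 9.95-fold, while Thy1, which T cells also express, fell 5.59-fold. That list moved up on set A (camera, adjusted p = 5.02e-05), with adjusted p = 0.348 with an estimated correlation.

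Most macrophage genes rose. Of 24 tested, 19 rose, none fell and 5 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.74. The scavenger receptor gene Marco rose 7.08-fold and the lysozyme gene Lyz2 4.76-fold. The list moved up on set A (camera, adjusted p = 1.13e-06, and adjusted p = 0.447 with an estimated correlation). Of 12 megakaryocyte and platelet genes 8 rose, none fell and 4 did not pass, with 9 rising adjusted over the list alone, led by the platelet chemokine gene Ppbp (9.33-fold) and Itga2b (2.76-fold). On set A the list test held 6 of these genes, without Ppbp and Itga2b, and did not pass with camera (adjusted p = 0.225). It passed with fry (adjusted p = 0.0204), which does not set the list against other genes. Of the 12 genes, 6 rose under either other scaling.

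Lymphocyte genes fell. Of 25 tested B cell genes none rose, 19 fell and 6 did not pass, and 21 fell when adjusted over the list alone. Fcmr, the IgM Fc receptor gene, fell 5.38-fold and Fcrla 3.72-fold. Of 22 tested T cell genes none rose, 17 fell and 5 did not pass, and 19 fell when adjusted over the list alone. The T cell receptor complex gene Cd3d fell 7.05-fold, from 912.6 ± 81 (SD, n = 2) to 53.5 ± 8.43 (SD, n = 3), and the interleukin 7 receptor gene Il7r fell 6.76-fold. All 11 tested NK cell genes fell, also when adjusted over the list alone, among them the inhibitory receptor gene Klra7 (5.87-fold) and the granzyme gene Gzma (4.81-fold). On set A the adjusted camera p was 2.86e-11 for B cells, 2.16e-11 for T cells and 1.83e-06 for NK cells, and on set B it was 2.43e-06 for B cells. With an estimated correlation the adjusted p values were 0.348, 0.26, 0.307 and 0.447. Ptprc, the pan-leukocyte marker CD45, fell 3.2-fold. Actb had a log2 fold change of -0.11 that did not pass (adjusted p = 0.361), and it was below 0 under both other scalings. With array weights it passed at -0.19 (adjusted p = 0.0179), and another Actb probe set had 0.07 (0.872).

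**Figure D2:**
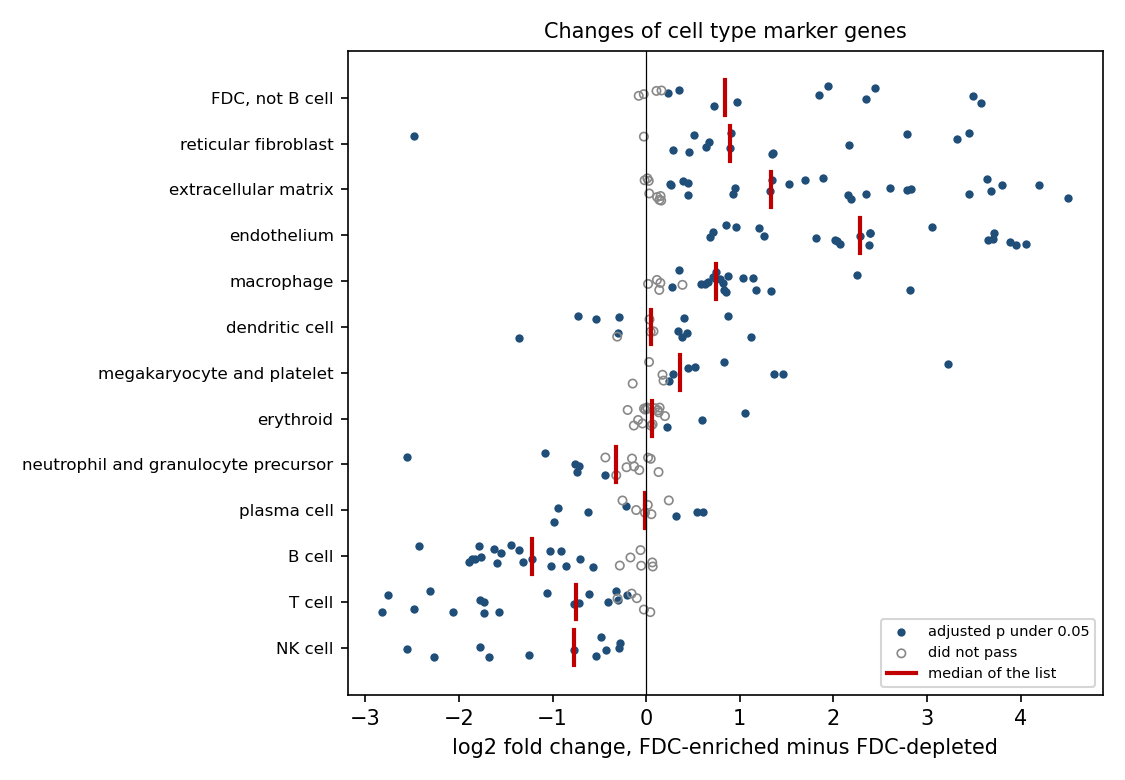
Log2 fold change (x axis, enriched minus depleted) of each tested gene in 13 marker lists (y axis), with filled points for adjusted p under 0.05, open points otherwise and a red bar at the list's median. All 21 endothelial genes lie above 0 with a median of 2.28, and the B cell, T cell and NK cell medians lie at -1.22, -0.75 and -0.77.

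Other blood cell lists were mixed. Of 26 tested immunoglobulin segments none rose, 20 fell and 6 did not pass, with 22 falling adjusted over the list alone; Ighv14-2 fell 9.19-fold and Igha 2.88-fold, and the list moved down on set A (camera, adjusted p = 2.43e-06, and adjusted p = 0.514 with an estimated correlation). Of 15 neutrophil and granulocyte precursor genes none rose, 6 fell and 9 did not pass, with 8 falling adjusted over the list alone, led by the calprotectin genes S100a8 (5.89-fold) and S100a9 (2.11-fold), and 9 fell under either other scaling. That list moved down on set A (camera, adjusted p = 0.00161, and adjusted p = 0.514 with an estimated correlation). Of 15 dendritic cell genes 6 rose, 5 fell and 4 did not pass, with 6 and 6 adjusted over the list alone. Bst2 rose 2.18-fold and Zbtb46 1.83-fold, whereas Ccr7, which guides cells to T cell zones, fell 2.57-fold and Batf3 1.66-fold. Of 13 plasma cell genes 3 rose, 4 fell and 6 did not pass, with 5 falling adjusted over the list alone. Prdm1 rose 1.53-fold and Ell2 1.46-fold, and Irf4 and Mzb1 fell 1.98- and 1.91-fold. Of 7 germinal centre B cell genes 1 rose, 3 fell and 3 did not pass, with the same counts adjusted over the list alone. Neil1 fell 2.11-fold and Bcl6 1.91-fold, and Plxnb2 rose 1.3-fold but did not pass without depleted sample 1 (adjusted p = 0.111) or under quantile normalization (0.0591). None of the dendritic, plasma and germinal centre B cell lists passed on set A (camera, adjusted p = 0.513, 0.796 and 0.73).

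Of 18 erythroid genes 3 rose, none fell and 15 did not pass, with the same counts adjusted over the list alone. Car2 rose 2.07-fold and Hba-a1 1.51-fold, the latter not passing without depleted sample 2 (adjusted p = 0.166). The erythroid median log2 fold change of 0.06 turned to -0.009 under quantile normalization and -0.01 with scaling to the median array, and the list did not pass on set A or B (camera, adjusted p = 0.609 and 0.987). With enriched sample 1 as the only enriched array it passed on set A (0.0411). Of 7 mast cell and basophil genes 2 rose, 1 fell and 4 did not pass, with the same counts adjusted over the list alone. Kit rose 1.69-fold and the histidine decarboxylase gene Hdc fell 1.55-fold. Gata2 rose 1.3-fold but did not pass without depleted sample 1 (0.111). None of 4 mesothelial and epithelial genes passed, also adjusted over the list alone. Of 30 cell cycle genes 1 rose, 2 fell and 27 did not pass, and none fell adjusted over the list alone; Bub1b rose 1.19-fold, and 7 fell under either other scaling. The falls of Mcm5 and Racgap1, 1.4- and 1.17-fold, were not stable. Mcm5 had adjusted p = 0.105 and 0.116 without depleted sample 1 or 2, and Racgap1 0.0875 and 0.145 without enriched sample 2 or 3. Racgap1 also had 0.199 with the replicate number as a block, 0.238 with enriched sample 1 as the only enriched array, 0.0561 with no filter, 0.0525 with no trend in the prior variance and 0.0569 with adjustment over all array sets. Another Mcm5 probe set, on set C, rose 1.24-fold.

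Most chemokine and adhesion genes rose, and 9 of 18 complement genes did. Of 22 chemokine genes 13 rose, 3 fell and 6 did not pass, with 4 falling adjusted over the list alone. Cxcl10, an interferon-induced chemokine gene, rose 12.4-fold and the neutrophil-attracting Cxcl1 12.1-fold at its brightest probe set, while Ccl6 and Ccl5 fell 2.02- and 1.7-fold. Of 23 adhesion genes 16 rose, 5 fell and 2 did not pass, with the same counts adjusted over the list alone. Jam2 and Nrp1 rose 7.08- and 7.05-fold, and the lymphocyte integrin genes Itga4 and Itgb7 fell 4.88- and 3.89-fold. Of 18 complement genes 9 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone, and C1s1 rose 5.9-fold. On set A these lists moved up (camera, adjusted p = 0.00296 for chemokines, 0.000471 for adhesion and 0.0115 for complement), with adjusted p = 0.348, 0.348 and 0.514 with an estimated correlation.

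Most genes for the uptake of apoptotic cells and 17 of 31 lysosome genes rose, and most MHC class II genes fell. Of 31 lysosome genes 17 rose, none fell and 14 did not pass, with 18 rising adjusted over the list alone, led by Cd63 (7.88-fold) and the cathepsin gene Ctsl (4.15-fold). Under quantile normalization 15 lysosome genes rose and 2 fell, and with scaling to the median array 15 rose and 1 fell. Of 16 genes for the uptake of apoptotic cells 12 rose, none fell and 4 did not pass, with 14 rising adjusted over the list alone, and the lipoprotein receptor gene Scarb1 rose 4.12-fold. The lysosome list moved up on set A (camera, adjusted p = 0.000277) and the uptake list on sets A (1.13e-06) and B (0.00388), with adjusted p = 0.514, 0.307 and 0.348 with an estimated correlation. Of 14 MHC class II presentation genes 1 rose, 11 fell and 2 did not pass, with 2 rising adjusted over the list alone. H2-Ob fell 4.15-fold and H2-DMb2 3.2-fold, and the costimulatory gene Cd86 rose 2.19-fold. That list moved down on set A (camera, adjusted p = 0.000101, and adjusted p = 0.479 with an estimated correlation).

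Signalling and stress lists held rises and falls. Of 31 immediate early and dissociation genes 19 rose, 6 fell and 6 did not pass, with 21 rising adjusted over the list alone. The inducible heat shock genes Hspa1a and Hspa1b rose 12.5- and 11.4-fold, and Btg1 and Klf6 fell 3.1- and 2.13-fold. Of 23 interferon response genes 11 rose, 4 fell and 8 did not pass, with 5 falling adjusted over the list alone. Rsad2 rose 3.43-fold, Tap1 fell 1.49-fold and Psmb8 1.37-fold, Psmb8 not passing without depleted sample 2 (adjusted p = 0.088). On set A these lists moved up (camera, adjusted p = 0.012 and 0.0115), with adjusted p = 0.514 and 0.479 with an estimated correlation. The interferon list did not pass with enriched sample 1 as the only enriched array (0.291). Of 20 lymphotoxin, TNF and NF-kB genes 7 rose, 5 fell and 8 did not pass, with the same counts adjusted over the list alone. Ltb, the lymphotoxin beta gene of lymphocytes, fell 6.95-fold and Ikbkb 1.74-fold, and Tnf rose 2.62-fold. Of these 20 genes 4 rose and 6 fell under quantile normalization, and 3 rose and 5 fell with scaling to the median array. Of 15 p53 response genes 4 rose, 3 fell and 8 did not pass, with the same counts adjusted over the list alone. Cdkn1a, a cell cycle inhibitor gene, rose 6.21-fold and Plk2 2.17-fold, while Sesn1 fell 3.94-fold and Trp53inp1 1.95-fold. Neither of these lists passed on set A (camera, adjusted p = 0.796 for each).

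Of 37 ribosomal protein genes 2 rose, 20 fell and 15 did not pass, with 21 falling adjusted over the list alone. Rpl13 and Rps26 fell 1.55- and 1.43-fold. The rises of Rps27l (1.27-fold) and Rps4l (1.26-fold) did not pass under either other scaling, nor without depleted sample 1 (adjusted p = 0.366 and 0.259), and Rps27l did not pass without enriched sample 1 (0.0633) or 2 (0.0932) or with no filter (0.0513). The list moved down on sets A and C (camera, adjusted p = 0.00161 and 0.00416), with adjusted p = 0.514 and 0.348 with an estimated correlation. The other lists tested on set B or C without a pass had adjusted camera p values from 0.18 to 0.987. On set A the shared FDC and B cell list (0.165), the cell cycle list (0.232) and the mast cell list (0.987) did not pass either. Over all 46 list tests, 16 passed upward and 9 downward with the preset correlation, and none with an estimated correlation (6 at an unadjusted p under 0.05). Fry, which does not set a list against other genes, passed 24 upward and 10 downward.

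Over all probe sets, the largest rises on set A beyond the genes above were Cxcl1 (18.6-fold at another probe set), Col18a1 (16.6-fold), the gap junction gene Gja1 (15.7-fold), Emp1 (14-fold), Igfbp7 (13.9-fold), the nuclear lamina gene Lmna (13.4-fold) and the matrix gene Sparc (12.8-fold). On set B they were Epas1, a hypoxia-inducible factor gene of endothelium (22.8-fold), Adgrf5 (15.05-fold), Lhfp (11.2-fold) and Bmp2 (9.97-fold). On set C they were Col4a2 (11.7-fold), the caveola gene Cavin2 (10.5-fold) and Tfpi, an inhibitor of coagulation (7.78-fold). The largest falls on set A beyond those above were Arhgap45 (6.12-fold), Tspan32 (5.63-fold), Cd8b1 (4.94-fold, over 2 enriched arrays), Snx5 (4.89-fold) and Ripor2 (4.73-fold). On set B they were Fuca1 (9.96-fold), Ms4a4b (8.37-fold), Tbc1d10c (6.39-fold) and Gimap3 (4.89-fold), and on set C they were Ralgps2 (7.59-fold), Dock2 (4.94-fold), Bach2 (4.88-fold) and Ccdc88c (4.26-fold). The probe sets of a gene did not always agree. Of 54 genes named by the rule that passed and had over 1 tested probe set, 16 had another probe set that did not pass. Among the genes of this paragraph, Fuca1 had a log2 fold change of 0.14 on set A (adjusted p = 0.212), Col18a1 0.01 at another set A probe set (0.965), Lmna -0.03 on set C (0.796) and Tfpi 0.06 at another set C probe set (0.529). The other set C probe sets of Ralgps2 had 0.07 and -0.16 and did not pass, while those on sets A and B fell 3.51- and 2.09-fold. Of the genes of earlier paragraphs, Plvap had -0.14 at another set B probe set (0.166), and on set C Apoe had -0.17 (0.0626), Acta2 0.12 (0.0896), Gzma -0.08 (0.409), Ccl6 -0.09 (0.271), Psmb8 0.02 (0.878), Ell2 0.00 (0.98) and Rps27l 0.11 (0.206). Igha had -0.03 on set B (0.746), and on set A another probe set of Madcam1 had 0.16 (0.169) and another of Mcm5 -0.06 (0.581).

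Passing probe sets of a gene also differed in size. Of the same 54 genes, 21 had another passing probe set with the same direction and a fold change over 2 times apart, Vcam1 and Ralgps2 among them. For genes that rose, the other fold changes were 4.52 for Eng, 3.6 and 3.22 for Sox17, 1.58 for Bgn, 1.91 for Col4a2, 4.74 for Hspa1a, 3.05, 3.39 and 4.36 for Col18a1 and 2.92 for Gja1. They were 1.62 for Lmna, 1.67 for Sparc, 2.64 for Epas1, 1.53 for Adgrf5, 4.6 for Bmp2 and 1.46 for Tfpi. For genes that fell they were 4.1 for Ighv14-2, 1.58 for Itgb7, 1.44 at each of 2 probe sets for Snx5, 2.21 for Ripor2, 1.84 for Gimap3, and 1.8 and 1.26 for Ccdc88c.

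In all, 3240 of 7895 tested probe sets (41%) passed on set A, 1824 higher and 1416 lower in the enriched fraction. On set B, 2838 of 7786 (36.5%) passed, 1513 higher and 1325 lower, and on set C 1341 of 7358 (18.2%) passed, 699 higher and 642 lower. At least 2-fold changes were mostly rises, with 493 rises and 218 falls on A, 274 and 126 on B, and 81 and 57 on C. At least 8-fold, set A had 49 rises and 2 falls. The balance of small changes depended on the scale, and the deposited scale kept the higher medians of the enriched arrays. Higher calls were 56.3% of calls on set A, and 41.5% (1447 higher, 2042 lower) under quantile normalization or 42.6% (1461 and 1966) with scaling to the median array. Set B had 53.3% higher, against 46.7% and 44.6%, and set C 52.1%, against 47.6% and 43.2%. Without depleted sample 1 or 2, set A had 2028 and 2038 calls. Set C had 808 without depleted sample 2, 882 without enriched sample 3 and 814 with enriched sample 1 as the only enriched array.

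For genes tested on more than 1 array set, the sets mostly shared direction where both passed, and less so over all genes. Of 1149 genes on A and B, 69% had the same sign, and 278 passed on both, 260 of them with the same sign. Of 1065 genes on A and C, 58.3% had the same sign, and 156 passed on both, 139 with the same sign. Of 1213 genes on B and C, 61% had the same sign, and 150 passed on both, 132 with the same sign. Across genes, which are not independent replicates, the fold changes had Pearson r = 0.572 and Spearman rho = 0.565 for A and B, 0.547 and 0.35 for A and C, and 0.46 and 0.342 for B and C. The same numbered samples were measured on each set, so this is not a replication in other samples.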

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

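The tests of explanations in this part were chosen after the results were seen. Some array controls, which the comparisons leave out, were brighter on every enriched array than on every depleted array of all 3 array sets. The enriched over depleted intensity, as a geometric mean over the sets, was 1.48 for the 3' Gapdh control, 1.66 for the 5' and 1.55 for the middle one. It was 1.38 for the control named MURINE_b1, 1.31 for MurFAS and 1.19 for MurIL10. These signals lie outside the gene comparisons, and no explanation was tested for them.

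The 18S ribosomal RNA control at the 5' end read the other way, with depleted over enriched ratios of 5.85 on set A, 7.98 on set B and 4.76 on set C. Single enriched arrays moved these ratios. The set A ratio was 26 without enriched sample 1, which read 5061 against 428.6 and 462.4 on the others, and the set B ratio was 17.3 without enriched sample 2 and 5.18 without 3. The 3' end control was also brighter in depleted arrays on sets B and C, by 3.41 times (6.91 and 2.26 without enriched sample 2 or 3 on B) and 2.44 times. On set A its ratio was 0.908, turned to 2.38 without enriched sample 1 and to 1.05 without depleted sample 1. The middle control differed less, by 1.32, 1.69 and 1.55 times on A, B and C. Brighter control transcripts on the depleted arrays fall short of the 5' difference, though not clearly of the middle one, as the biotinylated controls differed by at most 1.27 times on average over the controls of a set, and a single one by at most 1.49 times. The 3' actin control lay at 100% of the array maximum on sets B and C and at 84.2% or more on set A, so its ratio to the 5' control decides nothing. RNA degradation in the enriched fraction would raise its Gapdh 3' over 5' ratio, but the ratio was lower on every enriched array than on every depleted array of each set, narrowly on set A. Enriched over depleted it was 0.921 on set A, 0.904 on B and 0.851 on C, which argues against it for the Gapdh transcript. Degradation in the depleted fraction has that sign, but a ratio this near 1 does not decide whether any took place. Loss of 5' ends there would lower the 5' 18S control against the 3' one on depleted arrays. Their means were 11600 against 1606 on A, 11160 against 6720 on B and 9359 against 5769 on C. On enriched arrays they were 1984 against 1768, 1400 against 1972 and 1967 against 2366. These values argue against loss in the depleted fraction as the source of the 5' 18S difference. On every set the 5' control was lower against the 3' one on enriched than on depleted arrays. Loss of 5' ends in the enriched fraction would have that sign, opposite to the Gapdh ratio. Degradation in the enriched fraction is therefore not decided for 18S RNA. A difference between the fractions themselves stays open and was not tested.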

How the results depend on the processing

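The fits with enriched sample 1 as the only enriched array were chosen after seeing the data; the other settings were set before. No probe set called in the main analysis was called in the opposite direction under any setting. Requiring a 2-fold change left 711 calls on set A, 400 on B and 138 on C, by its construction. Leaving out 1 sample gave 2028 to 3670 calls on A, 1978 to 2491 on B and 808 to 1315 on C. Set A had 2028 without depleted sample 1 and 2038 without depleted sample 2, and C had 808 without depleted sample 2 and 882 without enriched sample 3, with fewer samples in each fit; a lone depleted array is assumed to vary like the enriched ones. Without enriched sample 2 or 3, set B had 2491 and 2416 calls, with the lone enriched array assumed to vary like the depleted ones. Enriched sample 1 alone gave 3709 calls on A and 814 on C, with the spread taken from the 2 depleted arrays and the lone enriched array assumed to vary like them. The cause was not tested. Of 46 list tests, 25 passed, and 0 with an estimated correlation (6 at an unadjusted p under 0.05). With fry, which asks another question, 34 passed. The form with an estimated correlation has few degrees of freedom, so its lack of passes decides little. With a sample left out, 36 to 45 of the list tests were run. Each kept its side of the threshold, and no list that passed changed direction. Turns of lists that passed in neither fit were not counted.

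The samples share a number on sets A and C but nothing pairs them. With the replicate number as a block, set A had 2812 calls and set C 865, and of the named genes Cd40 (adjusted p = 0.138), Ltbr (0.0832) and Racgap1 (0.199) lost the call. Enriched sample 3 has no depleted sample of its number, so the block absorbs it. The log2 fold changes are then those of the fit without enriched sample 3, such as -0.2024 for Cd40 and 0.2492 for Ltbr. The blocked fit is therefore not a separate check of these calls. Deviations of same-numbered samples correlated at 0.03 and 0.06 on A and at -0.31 and -0.15 on C. Set B shares only number 2, so no blocked fit was possible there.

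For named genes, 2301 of 2359 comparisons over 134 probe sets kept their direction and side of the threshold, 44 lost the call, 6 gained it and 8 reversed, and 113 probe sets never changed. The setting with the samples present on every set is the same fit as leaving out enriched sample 1. Its 105 comparisons, 1 of them a lost call, are thus counted a second time. The reversals were in genes that were not called. The log2 fold change was 0.0118 for Actb with enriched sample 1 alone. With a sample left out it ranged from -0.0511 to 0.1939 for Cd55, from -0.1404 to 0.0881 for Ntrk3 and from -0.1102 to 0.1297 for Serpina1a. Serpina1a had -0.0098 under quantile normalization, -0.0097 with median scaling and -0.0204 with the replicate block; the cause was not tested. For lists, 521 of 558 comparisons kept their side of the threshold, 26 lost the call, 25 of them with the estimated correlation, and 11 gained it. A turn in direction where neither fit passed counts among the 521. The plasma cell list on set A, down with camera and up with fry, is such a case. Signal over background limits the dim genes, whose fold changes are understated. Their size also depended on the setting. Over the settings the log2 fold change ran from 2.50 to 4.49 for Coch, from 2.80 to 4.48 for Cxcl13 and from 1.24 to 2.72 for Postn. For the brighter Clu it ran from 3.26 to 3.73.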

Other observations

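The gene family tests, the choice of Star and the tests of explanations in this part came after the data were seen. The single family members named here lie outside the rule, like Star, and none of these genes was put through the settings gene by gene. Genes were grouped by the stem of their symbol into 294 families of at least 6 tested genes, and Fisher's exact test, one-sided in each direction, asked whether more members passed than among all 12267 genes, of which 2357 rose and 1772 fell. After adjustment over families and directions, 2 families passed upward and 4 downward, with genes that are not independent. The Gimap family, small GTPases of lymphocytes, had 6 of 8 members that fell (adjusted p = 0.0228), with Gimap8 lower 3.34-fold and Gimap7 2.59-fold. The Smc family, subunits of cohesin, condensin and related complexes, had 5 of 6 that fell (0.0324), with Smc4 lower 2.41-fold and Smc6 1.66-fold. The Igkv family, kappa light chain segments, had 12 of 15 that fell (1.4e-05), and the Rps stem, which takes in kinases beside ribosomal proteins, 12 of 25 (0.00973). Upward, 8 of 9 Cxcl chemokines (0.00339) and 16 of 29 collagens (0.00339) rose. The semaphorins did not pass (adjusted p = 0.17), although 9 of 18 rose, among them Sema3g 8.21-fold and Sema4c 5.78-fold. The direction of each passing family's median was the same under quantile normalization and scaling to the median array. Star, a cholesterol transport gene of steroid-making cells that lies outside the rule, rose on all 3 sets, 7.56-fold on A, 8.85-fold on B and 2.59-fold on C at the brightest probe set of each.

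The endothelial genes rose more than macrophage, erythroid, FDC and reticular fibroblast markers. Their median log2 fold change exceeded that of the FDC list by 1.44 (permutation test, p = 0.0155, 0.0194 adjusted over 5 such differences), that of the reticular fibroblast list by 1.38 (permutation p = 0.0247, adjusted 0.0247) and that of the erythroid list by 2.22 (permutation p = 3e-05, adjusted 0.00015). It exceeded that of the macrophage list by 1.54 (permutation test, p = 1e-04, adjusted 0.00025). A loss of lymphocytes alone would raise other cell types alike only if their markers had no signal from the lost cells or from background. Such signal was not measured, and the pseudocount shrinks the change of dim genes. The gap therefore does not decide whether a loss of lymphocytes alone made the rise. The permutation tests of this part shuffle genes between lists and do not measure the spread between samples. Genes of a list are not independent (estimated correlation on set A 0.383 for endothelium and 0.441 for macrophages), so these p-values are too small. Scaling of the arrays does not remove the rise, since the lowest list median on set A was 2.08 under the other scalings. Endothelial cells in the enriched fraction are a candidate source, as 21 of 21 genes rose against 4 in the median random list matched on level, with Eng at 7161 and Cldn5 at 2935 in the enriched arrays. None of these genes is in another list, 5 of the 21 lay above the median level of all genes in the depleted fraction, and no sort that would remove such cells is given, but expression of the same genes by other stromal cells stays open.

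Most heat shock and immediate early genes rose in the enriched fraction, with 19 of 31 passing upward against 6 in the median random list matched on level, while 6 fell, such as Btg1 (3.1-fold) and Klf6 (2.13-fold), and 6 did not pass. The list passed upward on set A (camera, adjusted p = 0.012), but not with an estimated correlation (0.514), nor on set B (0.987), where the mean log2 fold change of its 6 genes was -0.20, or set C (0.18). With the replicate number as a block it passed upward on set C (camera, adjusted p = 0.0226). The count is consistent with a response to the isolation of the cells, in a test that macrophage or matrix genes would also pass. A difference in cell makeup alone stays open: all 5 heat shock members rose, but their median differed from that of the macrophage list by -0.17 (permutation test, p = 0.394). The labels say nothing of how either fraction was handled, so isolation and cell makeup cannot be told apart here.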
